A study of Mus musculus with 18 samples.

How the data were processed

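The series holds 18 ChIP-seq samples of 3T3-L1 cells, 6 each for PPARγ, RXR and RNAPII, on days 0, 1, 2, 3, 4 and 6 of differentiation. Per the labels' protocols, chromatin was fixed with formaldehyde, sheared by sonication, immunoprecipitated and sequenced on an Illumina Genome Analyzer. Samples were grouped by the antibody and day in their titles, which gives 1 library per group. The processed files covered the 6 RNAPII samples, and the other 12 samples were not analysed here. No label says whether the days came from 1 culture or several, so the spread between libraries may be technical.

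The authors deposited for each RNAPII library a list of tags as intervals of 200 bases, with no strand, and per the file names each sums 2 lanes. Every list held 5252311 tags, so the authors had brought the libraries to a common total, by a method not given in the sources used here. Per the file headers, the authors' table gives the number of tags inside the gene body, a whole count per gene and day, for 1631 Ensembl genes. Per the file headers it also gives log2 ratios of occupancy of each later day to day 0. These deposited log2 values equalled the log2 ratio of the deposited counts, with a count of 0 entered as 1. How the authors chose the genes, and the aligner, are not given in the sources used here. The build is not given in the sources used here either. The last tag on chromosome 1 ended at 197195432, which is the length of that chromosome in NCBI37 (mm9), and coordinates are printed as deposited. The gene names table in the box is of another assembly and was used for names only: 1536 of the 1631 symbols matched a current symbol or a unique synonym, and 20 intervals had no gene name. Symbols are printed as deposited.

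Tags were recounted over the deposited intervals. Tags lying wholly inside an interval gave the deposited count for 44.9% to 68.9% of genes, depending on the day, and log2 counts correlated at r of at least 0.996. Each recounted day matched the deposited column of its own day best. Of the listed genes, 71 overlapped another listed gene, and tags there cannot be assigned to a strand. Repeat tags at a position cannot be told from independent molecules, so intervals and floors cover counting error only.

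The listed-gene tags per library were 238520, 392710, 425602, 422962, 420918 and 196535 on days 0, 1, 2, 3, 4 and 6. As a measure of enrichment, 1000-base bins lying over 2000 bases from listed intervals were split into 14540 enriched bins (at least 100 tags over the 6 libraries) and 1860387 low bins (fewer than 15). Counts were scaled by TMM with the deposited library totals as sizes. Alternatives were the library total, DESeq2 median-of-ratios factors and, added after the data were seen, factors from the enriched bins outside the listed genes.

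A day against day 0 was described by log2 ratios after scaling, with a pseudocount of 1 tag, over 1619 genes with at least 50 tags in all. The 95% interval of a ratio came from the exact binomial interval of the tags of both days, without the pseudocount, and a count of 0 was given a floor of 3 counts. The slope on day was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on genes kept by filterByExpr with a minimum of 10 tags, with 4 residual degrees of freedom and a Benjamini-Hochberg threshold of 0.05. Its standard error was taken as the slope over the square root of the F statistic. A gene that rises and then returns to its level of day 0 can be missed by this test. Alternatives used DESeq2 1.42.0 and limma 3.58.1. The slope test was tried on simulated data for 1620 genes with the same levels. It recovered 11% of genes changing 2-fold over 6 days and 48% of those changing 4-fold, and called 2 of 1420 unchanged genes. In the simulation 200 genes changed along a straight line on the log scale, as many up as down, with a common dispersion of 0.0922. The genes of the table mostly varied, not all along a line, so these rates need not hold for them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

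Gene lists, the rule for named genes and the main settings were fixed before the data were examined. The rule names the 10 genes with the highest and the 10 with the lowest log2 ratio of day 6 to day 0 among those with at least 50 tags and a slope past the threshold. It also names the 4 members of each list with the largest absolute ratio, and a panel of 31 genes, of which 26 were in the table. That made 127 genes, of which the text prints those that matter for a comparison, and 1 value is not reported here. The 35 lists held 666 distinct genes, 231 of them in the table, and covered adipocyte lipid droplet and storage, fatty acid uptake and binding, fatty acid synthesis, triglyceride synthesis, lipolysis, fatty acid oxidation, adipokines, glucose uptake and glycolysis, TCA cycle, oxidative phosphorylation, branched-chain amino acid catabolism, peroxisome, early and late adipogenic regulators, inhibitors of adipogenesis and preadipocyte genes, extracellular matrix, actin cytoskeleton, DNA replication, mitosis, histones, glucocorticoid-induced genes, cAMP and immediate early genes, ribosomal proteins, ribosome biogenesis, interferon and inflammatory genes, unfolded protein response, macrophage markers, housekeeping controls, cholesterol synthesis, brown adipocyte, endothelial, skeletal muscle, osteoblast and cartilage and hepatocyte markers, and RNAPII and general transcription. Of these, 28 had at least 3 members and were tested. List counts describe listed genes only, since the rule that chose them is unknown.

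A list's value was the mean over members of the log2 level centred per gene. Its Pearson r and Spearman rho with the day were given exact two-sided p-values over the 720 orders, and the Pearson p was adjusted over the 28 lists. A list's median ratio was set against 10000 random lists of the same size from the table, matched on mean level in 10 bins. The share near the 5' edge used tags by their midpoint within 500 bases of the edge, and tags wholly inside the gene over 1000 bases from the edge, for 1446 genes of at least 2000 bases.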

Results

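RNA polymerase II (RNAPII) occupancy was followed through adipocyte differentiation of 3T3-L1 cells, a mouse embryonic fibroblast line that turns into fat cells when treated with a phosphodiesterase inhibitor, a glucocorticoid and insulin. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on days 0, 1, 2, 3, 4 and 6 with antibodies to PPARγ, RXR and RNAPII, which makes 18 samples. The 6 RNAPII libraries were analysed, 1 per day, and the 12 PPARγ and RXR samples were not analysed here. The stated purpose of the RNAPII libraries was to relate binding of the receptor pair to transcription, and the comparison open here is how gene occupancy changed with the day. Each library held 5252311 tags of 200 bases, a common total set by the authors, so the depth before that step is unknown. The authors' deposited table gave whole tag counts over the bodies of 1631 genes. With 1 library per day no difference between 2 days has a replicate check, and no p-value is given for such a difference. Intervals printed below cover counting error only.

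The share of tags in the listed genes was 4.54% on day 0, 7.48% on day 1, 8.10% on day 2, 8.05% on day 3, 8.01% on day 4 and 3.74% on day 6. Tags in genomic bins of low signal, taken as background, amounted on day 6 to 1.21 times those of day 0, and on days 1 to 4 to between 0.799 and 0.835 times. The day 6 library also had the largest share of tags at an already occupied position, 15.3% against 4.18% on day 0, though day 4 was close at 13.2%. Its file is named for other flow cells than those of days 0 to 4, so day 6 and its flow cells cannot be separated. Counts were scaled by the trimmed mean of M values (TMM) over the listed genes, which gave factors from 0.547 on day 6 to 1.36 on day 2. The factor of day 0 was 0.802. No background was subtracted, and dividing by these factors raises the background of day 6 further above that of day 0. Small rises on day 6 below can therefore hold background as well as occupancy, and their shares were not tested.

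**Figure D1:**
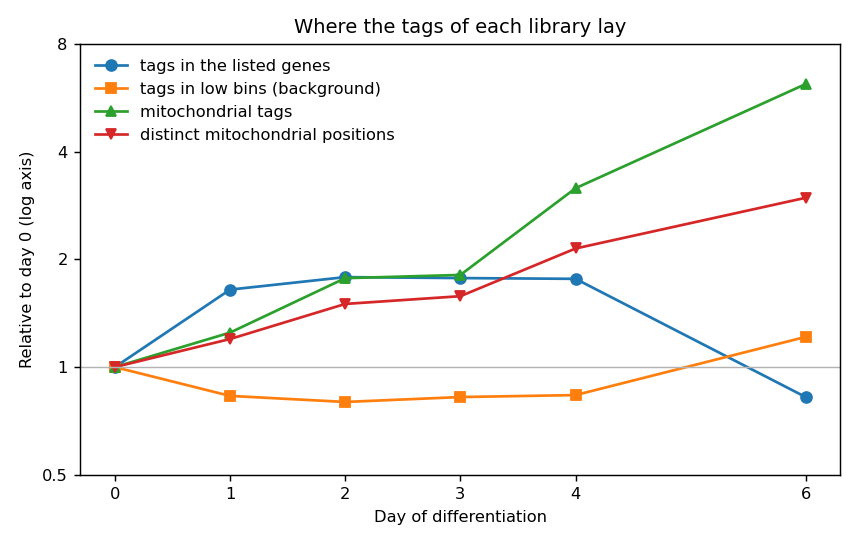
Tags of each RNAPII library relative to day 0 (log axis) against the day of differentiation, 1 library per point. Tags in the listed genes stood at 1.78 times day 0 on day 2 and 0.824 times on day 6, while mitochondrial tags reached 6.19 times.

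The highest log2 ratios of day 6 to day 0 among genes past the slope test were those of Scd1 (6.26), the stearoyl-CoA desaturase, Cidec (6.21), a lipid droplet protein, and the secreted adipocyte proteins Retn (5.32) and Adipoq (4.84). Cfd (4.45), the secreted factor adipsin, Ero1l (4.44), an oxidase of the endoplasmic reticulum, and Apoc1 (4.25), an apolipoprotein, were also among the highest 10. The other members of the highest 10 were Med16 (4.83), Ybx2 (4.66) and A530016L24Rik (4.62), and each lay next to another listed gene of high ratio. Med16 lay 2055 bases from Cfd, Ybx2 lay 686 bases from Slc2a4 (3.52), and A530016L24Rik lay 264 bases from Tmem179 (4.09), a neighbour named after its values were seen. Cfd and Apoc1 had 3 tags each on day 0, and their 95% counting intervals ran from 3.15 to 7.09 and from 2.95 to 6.91.

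The lowest log2 ratios of day 6 to day 0 among genes that fell belonged to S100a6 (−5.04), a calcium-binding protein with 122 tags on day 0 and 2 on day 6 and a counting interval from −8.44 to −3.50. Egr1 (−4.55), an immediate early transcription factor, Ptn (−3.54), the growth factor pleiotrophin, Maged2 (−3.53), S100a4 (−3.48) and Sox9 (−3.24), a transcription factor of cartilage and progenitor cells, were also among the lowest 10. So were the chemokine genes Ccl7 (−3.49) and Cxcl5 (−3.28), and Cyr61 (−3.10), a matricellular protein. Ifitm5 had 15 tags on day 0 and 0 on day 6, which is at least 3.41-fold lower when 3 counts are taken as the floor on day 6. Scd1 lay on chromosome 19 from 44468945 to 44481793, Cidec on chromosome 6 from 113374628 to 113385504, Adipoq on chromosome 16 from 23146942 to 23157813, Ptn on chromosome 6 from 36665663 to 36761111 and Egr1 on chromosome 18 from 35021111 to 35024610. These are the intervals of the deposited table, whose build is not given in the sources used here, and each covers the gene body with exons and introns together.

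Over the 1619 genes with at least 50 tags summed over the libraries, the genes at least 2-fold higher than on day 0 numbered 156 on day 1, 241 on day 2, 275 on day 3, 342 on day 4 and 364 on day 6. Those at least 2-fold lower numbered 175, 328, 290, 347 and 279 on the same days. The split depended on the scaling. With library totals as deposited, day 6 had 199 genes higher and 598 lower and a median log2 ratio of −0.40 against 0.13 with TMM, and day 2 had 771 higher and 118 lower. Scaled to enriched bins outside the listed genes, day 6 had 481 higher and 195 lower with a median of 0.36, and with DESeq2 size factors 269 higher and 411 lower.

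The slope of occupancy on the day was tested per gene with edgeR's quasi-likelihood test over the 6 libraries, in which the spread is the scatter around a straight line and not replicate error. Of 1625 genes tested, 183 passed at a 5% false discovery rate (Benjamini-Hochberg), of which 127 rose and 56 fell. The slope of Scd1 was 1.25 ± 0.24 log2 per day (SE, adjusted p = 0.0191) and that of Cidec 1.27 ± 0.29 (adjusted p = 0.0282). S100a6 fell by 0.79 ± 0.10 per day (adjusted p = 0.0088). The count rested on single libraries: 0 genes passed in edgeR without day 1, where the smallest adjusted p was 0.0555. There 437 genes had an unadjusted p under 0.05, among them all 183 genes, with the direction kept. The 183 genes were chosen on data that include these libraries, so this is not independent support. The genes passing numbered 101 without day 0, 92 without day 2, 58 without day 4 and 389 without day 6. With library totals 58 genes passed, 12 rising and 46 falling, so that the share of rising calls was 20.7% in place of 69.4%.

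**Figure D2:**
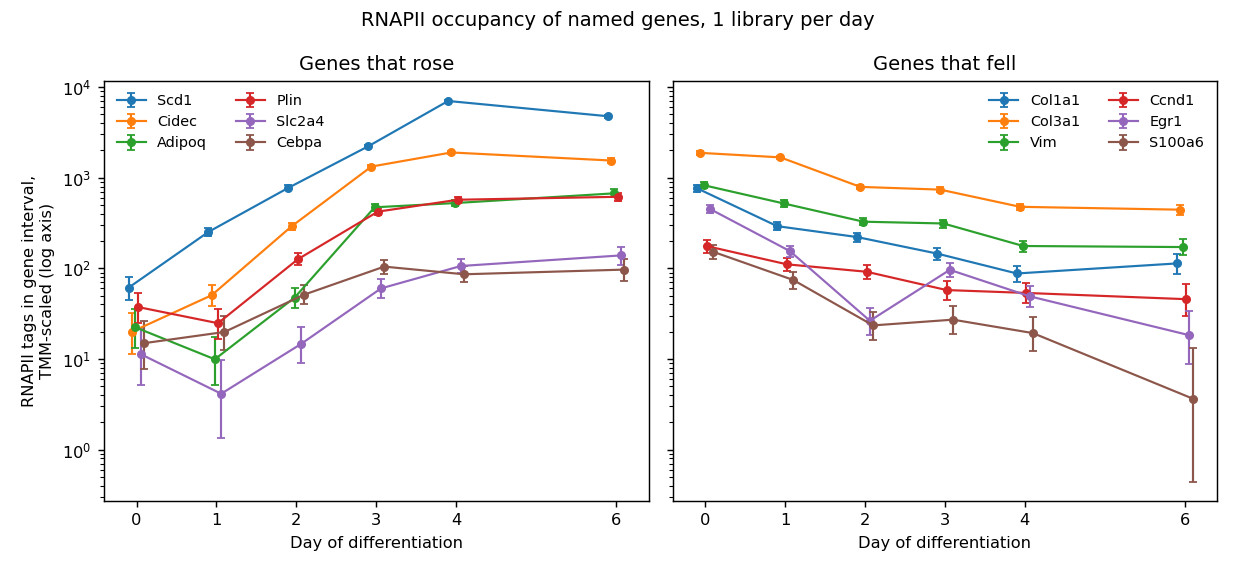
TMM-scaled RNAPII tags in the gene interval (log axis) against the day of differentiation for 6 genes that rose (left) and 6 that fell (right), 1 library per point. Bars are exact 95% Poisson intervals of the tag count; Scd1 had 49 tags on day 0 and 2609 on day 6, and Col1a1 had 611 and 62.

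Gene lists fixed before the data were examined were tested by the correlation of their mean centred log2 level with the day, with an exact two-sided permutation test over the 720 orders of the days. Of 35 lists, 28 had at least 3 members in the table. At a Benjamini-Hochberg adjusted p under 0.05 over these 28 lists, 11 rose and 1 fell. The Pearson r of the rising lists lay between 0.88 and 0.96 (adjusted p from 0.0333 to 0.0454) and Spearman's rho between 0.89 and 1 (exact p from 0.00278 to 0.0333). Over days 1 to 4 alone, which leaves out the days farthest from the median, r was between 0.91 and 1.00 for the same lists. Some lists that did not pass reached such values too, as the unfolded protein response (0.996) and adipokines (0.97). These 4 days therefore do not set the rising lists apart. The exact permutation p of the rising lists ran from 0.00139, the smallest this design can give, to 0.0194. Their adjusted p lay close to the threshold. With library totals 0 lists rose and 2 fell, the actin and the interferon and inflammatory lists, neither among the 12. With scaling to bins outside the listed genes 0 rose and 0 fell, where the adjusted p of the 12 lists was between 0.0722 and 0.0924. With a day left out the lists past the threshold were 5 without day 2, all rising, and 0 otherwise. There the smallest exact p is 0.00833, or 0.0167 without day 1 or day 6, so that 5 or 10 lists must reach it for any to pass, and the absolute r of the 12 lists was at least 0.82. The 12 lists kept their direction in each of these settings, but with library totals r was as low as 0.16, for the TCA cycle. The rule by which the authors chose the listed genes is not given in the sources used here, and if it used these libraries the lists are not independent evidence of direction.

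**Figure D3:**
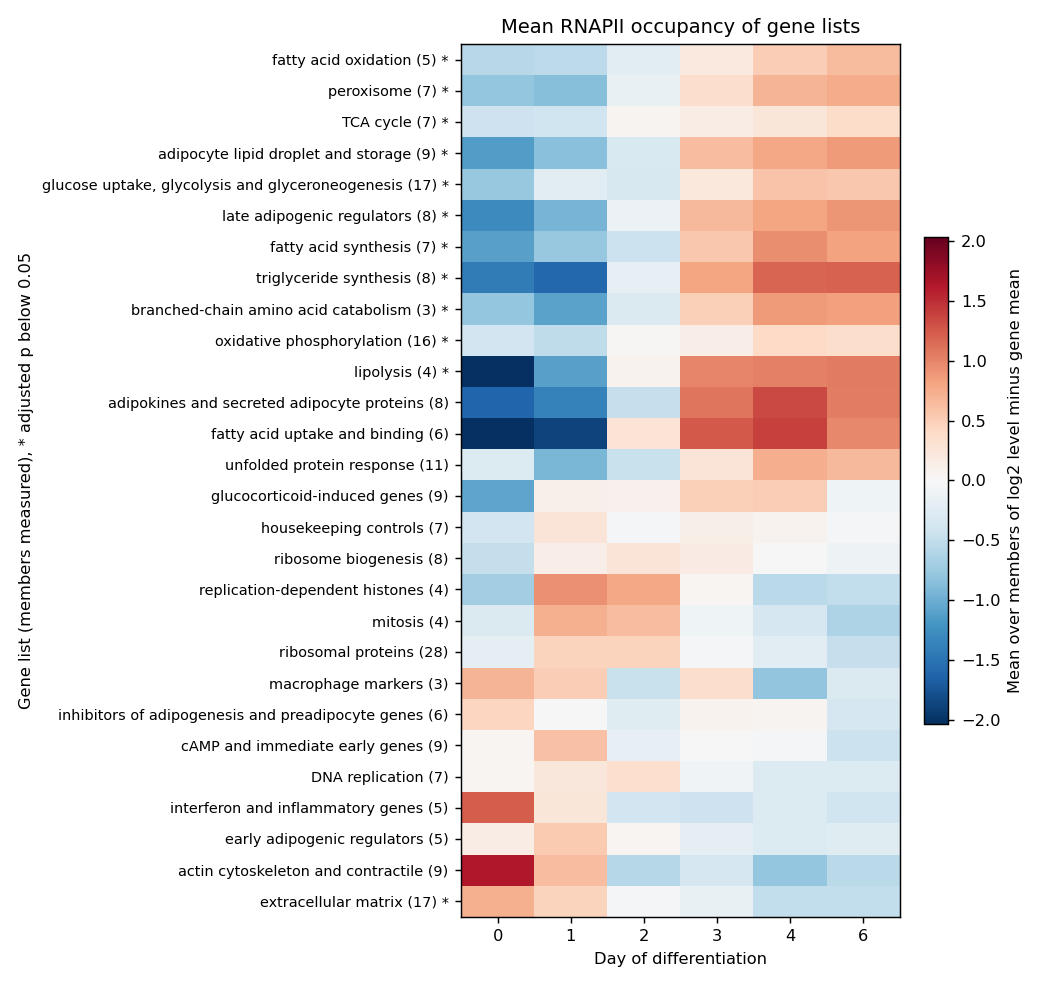
Mean over the measured members of each gene list of the log2 TMM-scaled level minus the gene's own mean (colour) for each day (columns), lists ordered by their correlation with the day and the number of measured members in brackets. Asterisks mark the 12 lists with an adjusted p below 0.05, 11 of them rising, and the actin list had the highest mean of any list, 1.63 on day 0.

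In the lipid droplet and storage list 2 of 9 measured members rose and 7 did not pass over all genes tested, against 5 rising adjusted over the list alone (r = 0.93, exact permutation p = 0.00556, adjusted p = 0.0333). Plin, the deposited symbol of Plin1, which coats lipid droplets, had a log2 ratio of 4.00 on day 6 and Cidec 6.21. Among triglyceride synthesis genes 5 of 8 rose, 7 adjusted over the list alone, among them Dgat2 (3.88), the diacylglycerol acyltransferase, Pnpla3 (3.50) and Lpin1 (3.01). The median log2 ratio of that list, 2.83, stood at the 100 percentile of 10000 random lists matched on level. For lipolysis 3 of 4 rose, and 3 adjusted over the list alone: Pnpla2 (3.57) and Lipe (3.44), the triglyceride and hormone-sensitive lipases, and Plin. The Lipe interval overlapped that of 4732471J01Rik, and without strand in the tag files these cannot be told apart.

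For fatty acid synthesis 2 of 7 members rose, also 2 adjusted over the list alone, and Fasn, the fatty acid synthase, had a ratio of 1.33 on day 6 and 2.19 on day 4 without passing (adjusted p = 0.106). For fatty acid uptake and binding 1 of 6 rose (Cd36, 3.11), against 4 rising and 1 falling adjusted over the list alone, and the list missed the threshold (r = 0.82, exact permutation p = 0.0458, adjusted p = 0.0881). Its members Acsl1, a long-chain acyl-CoA synthetase, and Fabp4, a fatty acid binding protein, had ratios of 5.69 and 5.21 but were highest on day 4, and their slopes did not pass (adjusted p = 0.0959 and 0.0636). Adipokines and secreted proteins had 5 of 8 members rising and 6 adjusted over the list alone, but the list missed the threshold (r = 0.87, exact permutation p = 0.0236, adjusted p = 0.0509). Agt, the angiotensinogen gene, was at 2.88 in that list. Lpl, the lipoprotein lipase gene, had a ratio of 2.48 (adjusted p = 0.0538), and Agpat2, an acyltransferase, 2.25 (adjusted p = 0.0995).

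Among late adipogenic regulators 5 of 8 measured members rose, 6 adjusted over the list alone, and the list rose (r = 0.92, exact permutation p = 0.00833, adjusted p = 0.0333). Klf15 (3.52) and Cebpa (2.62), transcription factors of mature adipocytes, rose. Pparg, the gene of the receptor that the study immunoprecipitated, had a ratio of 2.96 on day 6 and 3.17 on day 4, and its slope did not pass (adjusted p = 0.0524). Rxra, which encodes a partner of PPARγ, was highest on day 1, with log2 ratios to day 0 of 1.30 on day 1, 0.80 on day 3 and 0.29 on day 6, and −0.26 on day 6 with library totals. Early adipogenic regulators had 0 of 5 members past the test, also 0 adjusted over the list alone (r = −0.77, exact permutation p = 0.0667, adjusted p = 0.110). Cebpb and Klf5, which act early in the differentiation course, were highest on day 1 and had ratios of −0.32 and 0.13 on day 6, and Klf5 was at −0.42 with library totals. Fosl2 was also highest on day 1, with a ratio of −0.77 on day 6. Klf6 was highest on day 0, with a ratio of −1.08 on day 6. Egr2 was highest on day 4 (0.90) and had a ratio of 0.03 on day 6, and of −0.50 with library totals. Cebpd, Klf4, Pck1, Dlk1 and Fn1 were not among the listed genes and were not analysed here.

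For glucose uptake and glycolysis 4 of 17 members rose and 7 adjusted over the list alone, including Slc2a4 (3.52), the insulin-responsive glucose transporter, Hk2 (1.98) and Pgk1 (1.96), with r = 0.92 (exact permutation p = 0.0125, adjusted p = 0.0389). For oxidative phosphorylation 2 of 16 rose, 4 adjusted over the list alone, and the list median of 0.86 stood at the 99.9 percentile of random lists. The members that rose were Cycs (2.30), the cytochrome c gene, and Atp5g3 (1.72), while Cyc1 had a ratio of −1.27. The tricarboxylic acid cycle had 2 of 7 rising and 3 adjusted over the list alone (Mdh1, 1.97, and Idh3a, 1.91). Of its 7 members 6 were higher on day 6, while Idh2 had a ratio of −0.98. Fatty acid oxidation had 2 of 5 rising and 4 adjusted over the list alone, with Echs1 at 1.34. Peroxisome genes had 5 of 7 rising and 6 adjusted over the list alone, with Pex11a at 2.35 and Pex16 at 2.12. Catabolism of branched-chain amino acids had 2 of 3 rising and 3 adjusted over the list alone, Bcat2 (1.99) and Aldh6a1 (1.78). Gpd1, the glycerol-3-phosphate dehydrogenase, rose at 2.77. Some lists share members, as Plin stands in the lipid droplet and the lipolysis list.

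The extracellular matrix list had 17 measured members, of which 2 fell and 15 did not pass, against 7 falling adjusted over the list alone (r = −0.93, exact permutation p = 0.00833, adjusted p = 0.0333; rho = −0.94, exact p = 0.0167; r = −0.98 over days 1 to 4). Col1a1 (−2.74) and Col3a1 (−2.08), the fibrillar collagens, fell, and Lox (−3.30) and Col1a2 (−2.49) had low ratios without passing (adjusted p = 0.0570 and 0.0588). The median of the list, −1.19, lay below all 10000 random lists. The actin and contractile list had 0 of 9 members higher on day 6, and 3 fell, 8 adjusted over the list alone, but the list did not pass (r = −0.79, exact permutation p = 0.0611, adjusted p = 0.107). Its mean log2 ratio was −2.21 on day 2 and −2.19 on day 6. Vim (−2.26), the vimentin gene, and Cyr61 fell, and Acta2, smooth muscle actin, had a ratio of −3.59 (adjusted p = 0.0630). Of the preadipocyte genes and inhibitors of adipogenesis 1 of 6 rose (Foxo1, 1.79) and 2 fell (Sox9 and Twist1, −2.87), with the same counts adjusted over the list alone (list r = −0.68, exact permutation p = 0.125, adjusted p = 0.170). Ccnd1, a cyclin of the G1 phase, fell at −1.92.

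Several lists were highest in the middle of the course and did not pass. Replication-dependent histones stood 1.64 above day 0 on day 1 in mean log2 level and 0.21 on day 6 (4 members, r = −0.33, adjusted p = 0.538). Mitosis genes stood 1.03 above day 0 on day 1 and at −0.33 on day 6 (4 members, r = −0.57, adjusted p = 0.275). DNA replication genes stood 0.30 above day 0 on day 2 (7 members, r = −0.74, adjusted p = 0.139). Ribosomal protein genes stood 0.64 above day 0 on day 2 and at −0.28 on day 6, and 1 of 28 fell (Rpl10a, −1.55), 0 adjusted over the list alone (r = −0.59, adjusted p = 0.267). Ribosome biogenesis was 0.75 above day 0 on day 2 (8 members, r = 0.22, adjusted p = 0.679). Housekeeping controls stood 0.65 above day 0 on day 1, 0.33 on day 2 and 0.34 on day 6. An early rise of the size seen in the ribosomal lists was thus not particular to them. No member of the histone, mitosis, replication or biogenesis lists passed, over all genes or adjusted over the list alone. Many ribosomal protein and histone genes have near copies in the genome, so their counts are uncertain. Glucocorticoid-induced genes were at 1.17 on day 1, 1.57 on day 4 and 0.98 on day 6, with 0 of 9 past the test in either adjustment (r = 0.51, adjusted p = 0.338). In that list Fkbp5, a glucocorticoid-induced co-chaperone, was at 2.29 on day 4 and 1.14 on day 6, and Ddit4 at 2.32 and 1.87. These p-values are from the same exact permutation test.

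Among cAMP-responsive and immediate early genes 2 of 9 fell, 2 adjusted over the list alone (Egr1 and Nr4a1, −1.55), and Rgs2, a regulator of G protein signalling, had a ratio of 3.36 without passing (adjusted p = 0.327; list r = −0.69, exact permutation p = 0.128, adjusted p = 0.170). Interferon and inflammatory genes had 3 of 5 members falling, 3 adjusted over the list alone: Ccl7, Cxcl1 (−2.22) and Cxcl12 (−2.05). That list did not pass (r = −0.75, exact permutation p = 0.0875, adjusted p = 0.136), and its median of −2.05 stood at the 0.06 percentile. The unfolded protein response list had 1 of 11 rising (Dnajb9, 2.56), 4 adjusted over the list alone, and missed the threshold (r = 0.82, exact permutation p = 0.0472, adjusted p = 0.0881). Housekeeping controls had 1 of 7 rising (Pgk1), and 1 rising and 1 falling adjusted over the list alone (r = 0.26, exact permutation p = 0.632, adjusted p = 0.655). Of the usual reference genes Gapdh had a ratio of 1.18 and Actb −1.94, and neither slope passed (adjusted p = 0.142 and 0.0720).

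Markers of other cell types were sparse in the table. Macrophage markers had 3 measured members with a median ratio of −1.34, and none passed over all genes or adjusted over the list alone (r = −0.67, exact permutation p = 0.158, adjusted p = 0.202). Endothelial, skeletal muscle and hepatocyte markers had 0 members in the table. Osteoblast and cartilage markers had 1 (Sox9, which fell), brown adipocyte markers 2 with 0 past the test, cholesterol synthesis 2 with 1 rising (Insig1, 2.18), and RNAPII and general transcription 2 with 0 past the test. These last lists were too short for the list test. On day 6, 8 of 28 list medians lay above the central 95% of matched random lists and 4 below it, where 1.4 in all are the number given by chance. Of the 11 rising lists 5 lay inside it: the TCA cycle (81.48 percentile), branched-chain amino acid catabolism (92.53), lipid droplet and storage (94.84), fatty acid synthesis (95.38) and fatty acid oxidation (97.02).

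The day of highest occupancy was read for the 1168 genes that varied at least 2-fold. It was day 0 for 394 genes, day 1 for 165, day 2 for 110, day 3 for 73, day 4 for 176 and day 6 for 250. Where the highest day had to exceed the next by 1.5-fold, 236 genes remained for day 0, 40 for day 1 and 37 for day 6, and 3, 2 and 8 for days 2, 3 and 4. With library totals 1614 genes varied at least 2-fold, of which day 2 held 450 and day 6 held 9, so this order depends on the scaling.

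The authors' deposited table gave log2 ratios of each day to day 0 that equalled the log2 of their count ratios for all 1631 genes to within 1e-09. By these ratios 784 genes were at least 2-fold higher on day 2 and 125 lower, and on day 6 203 were higher and 613 lower in the authors' deposited table. For 1614 of the 1631 genes the largest absolute ratio in the authors' deposited table was at least 1, so the table holds genes that varied and its counts do not describe the genome. Ratios recomputed from the tags correlated with the authors' deposited table at r = 0.995 to 0.999 across genes, which are not independent replicates.

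RNAPII near the 5' edge of the genes made up a smaller share of the tags on later days. Tags within 500 bases of the edge were 19.9% (95% exact binomial interval 19.8 to 20.1) of those plus the tags over 1000 bases inside the gene on day 0, over 1446 genes. The share was 16.7% on day 1, 14.1% on day 2, 13.4% on day 3, 10.6% (10.6 to 10.7) on day 4 and 13.1% (13.0 to 13.2) on day 6. The share of the median gene went the same way, from 29.0% on day 0 to 19.8% on day 4 and 22.5% on day 6. The densest tags lay within 300 bases upstream of the edge, with 75.7 tags per kb on day 0. The deposited intervals thus begin downstream of the promoter-proximal peak. The difference between days has no replicate check. Tags over 1000 bases inside the gene numbered 209839 on day 0 and 385322 on day 4. Those near the edge numbered 52233 on day 0, 70339 on day 1 and 45901 on day 4. Because the table holds genes whose body counts varied, a change in the share can follow from the choice of genes. On day 6 the share cannot be separated from the higher background of that library.

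**Figure D4:**
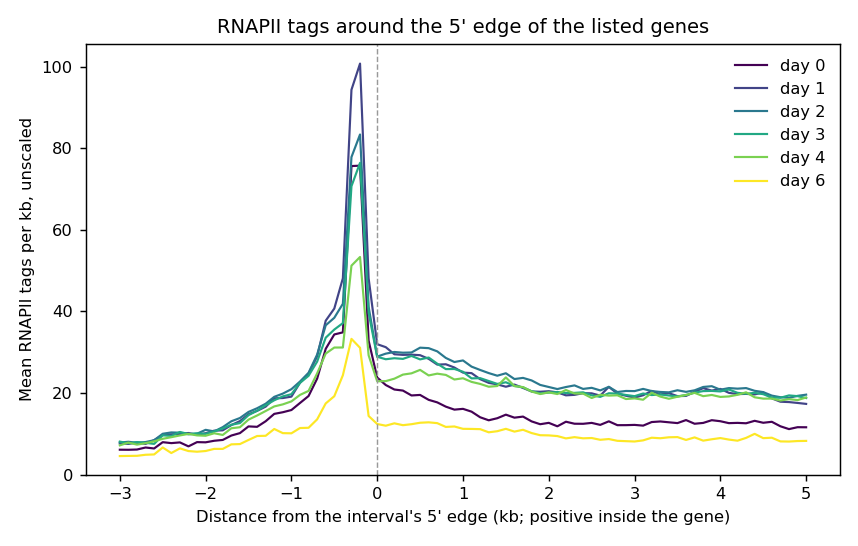
Mean unscaled RNAPII tags per kb over the 1631 genes against the distance in kb from the 5' edge of the deposited interval (dashed line), 1 line per day. The peak upstream of the edge reached 101 tags per kb on day 1 and 33.3 on day 6.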

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

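All tests in this part were chosen only after the result was seen. What stood out were tags on the mitochondrial genome and in single bins outside the listed intervals, whose own changes no comparison of the report describes.

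Tags on the mitochondrial genome numbered 3458 on day 0 and 21389 on day 6, 6.19 times as many in libraries of equal total, and rose with the day (r = 0.93, exact permutation p = 0.00139, the smallest this design can give; rho = 1, exact p = 0.00278; r = 0.91 over days 1 to 4). More background in the later libraries would raise mitochondrial and low-signal nuclear bins alike, but the mitochondrial ratio exceeded the low-bin ratio on every later day, with a median quotient of 2.22. Repeat reads at the same positions cannot be the whole cause, because distinct mitochondrial positions also reached 2.97 times those of day 0. A candidate explanation that stays open is more mitochondrial DNA in later cells, for which the r of 0.9305 with the day is what was seen. With 1 chromatin preparation per day this cannot be told apart from a change in how much mitochondrial DNA entered the preparation.

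Outside the listed intervals, 399 of the 14540 enriched bins held at least 4-fold more tags on both day 4 and day 6 than on day 0, and 120 held at least 4-fold fewer, after scaling to those bins. The longest run of higher bins lay on chromosome 6 from 115312001 to 115366000, ending 6333 bases from the listed interval of Pparg, with log2 ratios to day 0 of 3.67 on day 4 and 2.94 on day 6 after that scaling (318, 4086 and 1417 tags on days 0, 4 and 6). The next lay on chromosome 8 from 47624001 to 47636000, 2596 bases from the listed interval of Acsl1, with 6.67 and 5.70 (40, 4215 and 1235 tags). A listed interval need not cover its whole gene, and no annotation of the build was used. Whether these 2 runs are parts of Pparg and Acsl1 or separate regions therefore cannot be told here. The longest run of lower bins lay on chromosome 1 from 164146001 to 164157000, with −2.92 and −3.55 (1767, 235 and 87 tags), and the next on chromosome 2 from 117937001 to 117946000, with −5.02 and −4.12 (1092, 33 and 36 tags).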

How the results depend on the processing

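The alternatives that scale to bins outside the listed genes, recount tags, leave out overlaps, or read the highest day under library totals or without day 6 were added after the data were seen. No paired analysis was possible because each day has 1 library.

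All 183 genes past the slope test kept their direction under each of the 18 other settings in which they were fitted. These settings reuse the libraries on which the genes were chosen, so the kept direction is not independent support. Of the 58 named genes that passed, 19 still passed with library totals, 34 with DESeq2 size factors, 37 without the first 1000 bases and 44 with tags outside overlaps. Leaving out each day kept 0 (without day 1) to 56 (without day 6) of them, and 51 to 58 passed with the DESeq2 Wald test, limma, distinct positions, recounted tags, the rank of the day, either filter or the outside scaling. The count of 183 became 58 with library totals, 109 with DESeq2 size factors, 350 with the DESeq2 Wald test and 366 with the rank of the day. Rising genes, 127, became 12, 67, 251 and 237 in the same order, and 80 without the first 1000 bases. Falling genes, 56, became 99 with the Wald test and 129 with the rank of the day. Leaving out each day gave 0 (without day 1) to 389 (without day 6) genes, 0 to 200 rising and 0 to 189 falling. The cause was not tested, here or for the values below.

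For RNAPII day 6 against day 0 per gene, the genes at least 2-fold higher, 364, became 199 with library totals, 574 at 1.5-fold and 109 at 4-fold, and those lower, 279, became 598, 570 and 63. In the authors' deposited table, 203 higher became 310 at 1.5-fold and 68 at 4-fold, and 613 lower became 151 at 4-fold. Rising lists, 11, became 3 with medians over members, 0 with library totals and 0 with outside scaling, and falling lists, 1, became 2 with library totals, 3 with the square root of day and 0 with outside scaling. Leaving out each day gave 0 to 5 rising and 0 to 0 falling lists, where the exact test on 5 libraries cannot go below p = 0.00833. Medians, square root of day, outside scaling and library totals turned no called list around.

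For the day of highest occupancy, read over 1168 genes, other settings changed the counts. With a lead of 1.5-fold over the next day, days 0, 1, 2, 3, 4 and 6 held 236, 40, 3, 2, 8 and 37 genes, by construction fewer. With library totals they held 260, 343, 450, 215, 337 and 9 of 1614 genes. With outside scaling days 0, 2, 4 and 6 held 246, 248, 381 and 163 of 1291 genes. Without day 6, day 4 held 314 of 1051 genes. The share near the 5' edge was 12.6, 10.2, 8.40, 7.94, 5.97 and 6.95% with a window of 250 bases and 27.7, 23.8, 21.4, 20.3, 17.3 and 20.2% with 1000 bases, lowest on day 4 in each.

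Depth limits genes of few tags most: S100a6, Cfd and Apoc1 rest on 2 or 3 tags on a day. The slope test recovered 11% of simulated 2-fold changes, so genes that did not pass are not shown to be steady.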

Other observations

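All tests in this part were chosen only after the result was seen, and the genes named in the next paragraph were chosen after their values were seen.

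Some genes had a higher RNAPII level on day 1 than on every other day. Of the 40 genes whose day 1 level exceeded that of every other day by 1.5-fold, the lead over the next day was largest for Gas6 (1.58 in log2), a growth-arrest-induced ligand, Vcan (1.27), the matrix proteoglycan versican, 1700038P13Rik (1.12), Ube2c (1.12), a mitotic ubiquitin-conjugating enzyme, and Slc6a6 (1.11), the taurine transporter. The 1700038P13Rik interval overlaps that of Cyp1b1, also in the set, and their shared tags cannot be assigned without strand. Fosl1 (0.88) and Snai1 (0.87), transcription factors, Dusp6 (0.90), a MAP kinase phosphatase, and Id3 (1.05), an inhibitor of basic helix-loop-helix factors, were in the same set. Scaled to bins outside the listed genes, Gas6 led by 1.49 and Vcan by 1.09. The smallest lead there was that of Rdm1 (0.42), which is under 1.5-fold, so not all 40 genes kept the rule. On day 2 alone the set held 3 genes, led by Hspa8 (0.88), a heat shock cognate chaperone. On day 4 alone it held 8 genes, led by Izumo1 (1.58) and Vkorc1 (0.83). Slc7a5 (0.77), an amino acid transporter, and Dgat2 (0.71) were also in the day 4 set.

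Neighbouring listed genes changed alike over the days. Tags shared by overlapping intervals cannot be the whole cause, since pairs of genes 200 to 10000 bases apart had a median profile correlation of 0.77 against −0.02 for random pairs on other chromosomes. Polymerase running past gene ends would make convergent and same-strand pairs more alike than divergent pairs: convergent pairs were, by 0.309 in mean correlation (two-sided permutation p = 0.00042 over 100000 resamples, 105 and 43 pairs). Same-strand pairs exceeded divergent pairs by 0.0835 (two-sided permutation p = 0.362, 125 pairs) and had the lower median, 0.6215 against 0.6703, so this explanation stays open. Divergent pairs had a mean correlation of 0.3957 (one-sided permutation p = 2e-05 against random pairs), so shared regulation of neighbours may contribute, though pairs that share a gene are not independent.

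The listed genes held fewer tags on day 6 than on day 0. With repeats dropped everywhere, listed genes held a share of distinct positions 0.838 times that of day 0 (95% counting interval 0.833 to 0.843). With all tags kept the ratio was 0.824, so dropping repeats on both days closed little of the difference. The ratio would be 0.962 if day 6 repeats were kept inside the listed genes and all other repeats of both days dropped. That value treats the 2 days unlike and is a bound only. Repeats cannot be told from independent molecules, so how much of the difference repeat reads at the same positions make up stays open. A lower enrichment of the day 6 library is consistent with the median log2 ratio of −0.74 over enriched bins outside the listed genes. An overall fall in polymerase occupancy could give the same values, low bins at 1.21 times day 0 included, and these cannot be told apart with 1 library on its own flow cells.

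Of 101 orders of the 6 days, the real order included, 2 gave at least the 183 genes past the slope test. The other of these gave 224 genes, with an order that correlated with the real days at r = 0.7. For 1614 of the 1631 genes the largest absolute deposited log2 ratio to day 0 was at least 1. The choice of genes may thus set day 0 apart. The days are then not interchangeable, and 2 of 101 is not a p-value.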
